A study of Homo sapiens with 75 samples.

How the data were processed

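Primary human trophoblast cultures from normal term placenta were treated with DMSO as control, with 10 µM troglitazone or with 1 µM GW7845. Both compounds are agonists of PPARG, a nuclear receptor. Treatment began 5 h after plating and lasted 48 h. Per the labels, each RNA sample was pooled from 3 placentas, and targets were made from 30 µg of total RNA by Affymetrix's standard procedures. There were 5 pools per treatment and 5 Affymetrix array types, named 95a to 95e, which gave 75 arrays. Arrays of the same treatment and replicate number were taken as 1 pool. Their descriptions are identical, but dose, times, placentas per pool and RNA amount are the same for all replicates of a treatment. The match thus rests mainly on the number in the titles. In 150 comparisons across array types, deviations from the treatment mean correlated best within the own pool in 33, against 10 by chance (median correlation 0.0505). The list tests, means over array types and fits that left out a pool rest on this match. The labels do not say whether pools of different treatments shared placentas. The sample information gives the number of placentas per pool and not which ones. All tests treat the 5 pools of a treatment as independent.

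The deposited values are intensities on a linear scale, with 1 value per probe set. The authors had scaled every array: the mean of the values between the 2nd and the 98th percentile was near 1500 on 95a, 95c, 95d and 95e and near 500 on 95b, where it ran from 499.64 to 499.72. The software, the summary of probes to probe sets and the scaling target are not stated. No genome build belongs to these tables, so no coordinates are given. For arrays, the number of arrays limits the precision.

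Values were used as deposited because the trimmed means of the 15 arrays of a type agreed within 5%. A floor was set at 5% of the trimmed mean (75 intensity units, or 25 on 95b), and values were put on the log2 scale. Probe sets were kept when their mean over the 15 arrays reached 20% of the trimmed mean (300 units, or 100 on 95b). Of 63174 probe sets, 39087 matched a single gene symbol, 1036 several and 23051 none. Of the 63174, 335 control probe sets and 84 probe sets of sex-linked genes were left out. The filter kept 43813 probe sets, of which 28318 matched a single gene. Each of 14708 genes was represented by its kept probe set with the highest mean over all 15 arrays.

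Each array type was fitted in limma 3.58.1 under R 4.3.3, with a mean per treatment, 12 residual degrees of freedom and a mean-variance trend in eBayes. Benjamini-Hochberg adjustment ran over all 43813 probe sets together, and a gene changed when its adjusted p was under 0.05. Tests are two-sided. The 3 comparisons were troglitazone minus control, GW7845 minus control and GW7845 minus troglitazone. All comparisons with control share the same 5 control pools. Replicate numbers were not used as pairs. A fold is the antilog of the difference of mean log2 values.

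There were 31 gene lists, 23 for pathways and 8 for cell types, tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the 31 lists. The same test with an estimated correlation, and limma's fry, were run alongside. Of 814 genes on the lists, 615 had a kept probe set, 105 lay under the filter and 94 had no probe set of their own. The mean of a list's genes in each pool was also compared by a two-sided exact permutation test over 252 splits of 5 against 5 pools, whose smallest p is 0.0079. Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names PPARG, up to 8 genes with the largest rise and 8 with the largest fall among changed genes whose 5 pools lay on 1 side of the other group's mean, and up to 3 changed members of each list. Where a list changed with no changed member, its pair of members with the smallest p is named. Where no gene changed, the 4 genes with the smallest p are named.

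The correlation of fold changes between the ligands was set against simulated values with no change under either ligand and against fits with the control pools split between the ligands. Alternatives covered normalisation between arrays, floor, filter, the variance trend, array weights, the probe set chosen, the span of the multiple-testing adjustment, the samples in the fit, a replicate block and leaving out each pool. A fit without the 3 pools that correlate least with the others, and a contrast of both ligands with control, were added after the data were seen. Data were simulated with each probe set's own mean and SD and with no correlation between genes. On these data the gene test recovered 4.48% of genes changed 1.5-fold, 23.9% changed 2-fold and 40.9% changed 3-fold, with 1 false call among 14708 genes. It called 0 genes in a simulated comparison with no change. A simulated list of 30 genes shifted by 0.3 had an adjusted p of 2.4e-07 in camera, and 0 unshifted lists were called. Genes of some real lists were correlated, with estimates of 0.094 for interferon response and 0.183 for oxidative phosphorylation. The simulation therefore does not show how often camera calls an unchanged list in these data. Estimates were lower for fatty acid oxidation (0.03), the cell cycle (0.009) and PPAR targets (-0.002). The cell cycle and PPAR target values lie under the preset 0.01, so a larger correlation does not explain their loss with an estimated correlation.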

Results

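Gene expression was measured in cultured human trophoblasts, the epithelial cells of the placenta, after 48 h with DMSO, 10 µM troglitazone or 1 µM GW7845. Each treatment had 5 pools of RNA from 3 placentas each. The arrays held 63174 probe sets on 5 array types, and 14708 genes could be tested. The median correlation of an array with the other arrays of its type was 0.889 on 95a, 0.804 on 95b, 0.778 on 95c, 0.739 on 95d and 0.752 on 95e. Values below are log2 intensities with SD over n = 5 pools unless another error is named.

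The ratio of the 3' to the 5' probe sets of ACTB, a measure of RNA and target quality, differed with treatment. Its mean over the array types was 1.19 ± 0.036 (SD, n = 5) in control pools. With troglitazone it was 1.34 ± 0.097 (exact permutation p = 0.0159), and with GW7845 it was 1.44 ± 0.032 (exact permutation p = 0.00794). The same ratio for GAPDH was 1.55 ± 0.057 in control pools, 1.64 ± 0.18 with troglitazone (exact permutation p = 0.349) and 1.46 ± 0.11 with GW7845 (exact permutation p = 0.135). The pools that correlated least with the others were troglitazone replicate 3 (mean correlation 0.767), troglitazone replicate 2 (0.773) and GW7845 replicate 4 (0.777).

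The comparison of troglitazone with control asked which genes respond to a PPARG agonist in these cells. The placental hormone gene CRH rose 2.87-fold and PLIN2, which encodes a coat protein of lipid droplets, rose 2.55-fold. INSIG1, a brake on SREBP processing, rose 2.37-fold, CPT1A, the gate enzyme of mitochondrial fatty acid oxidation, rose 2.34-fold, and HMOX1, which degrades heme, rose 2.15-fold. PPARG itself, the receptor of the ligand, fell 2.12-fold. In all, 28 genes changed, 11 up and 17 down, and 54 probe sets, 23 up and 31 down.

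CRH (measured on 95a) stood at 14.29 ± 0.20 with troglitazone and 12.77 ± 0.18 in control, a difference of 1.52 (SE 0.13, adjusted p = 2.06e-05). PLIN2 (95a) stood at 14.38 ± 0.28 against 13.03 ± 0.12, a difference of 1.35 (SE 0.13, adjusted p = 4.83e-05). For INSIG1 (95a) the difference was 1.25 (SE 0.18, adjusted p = 0.00475), and for HMOX1 (95a) it was 1.10 (SE 0.13, adjusted p = 0.000718). CPT1A (95d) differed by 1.23 (SE 0.23, adjusted p = 0.0365), and its 6 other probe sets had the same sign with a mean of 0.37. PPARG (95a) stood at 9.85 ± 0.21 against 10.94 ± 0.12 and fell by 1.08 (SE 0.20, 95% interval -1.49 to -0.68, adjusted p = 0.03). Its mean intensity was 925.5 with troglitazone and 1963 in control. The other large rises were SOWAHC (2.10-fold), LIMCH1 (1.92-fold) and DTX4 (1.63-fold). The other 3 probe sets of LIMCH1 had a mean of -0.14, and 2 of them had the sign of the rise. Rises of the transcription factor CEBPA (1.53-fold) and the phosphate transporter SLC20A1 (1.61-fold) were smaller.

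Among genes lower with troglitazone, TGFBR1, a receptor of transforming growth factor beta, fell 2.98-fold (SE 0.30 on the log2 scale, adjusted p = 0.0396). Its level was 9.35 ± 0.88 with troglitazone, where replicate 2 lay lowest at 7.80, and 10.92 ± 0.26 in control. With 1 pool left out at a time, its log2 change was -1.19 at the smallest, and its 4 other probe sets had a mean of -0.56, 3 of them with the same sign. CLDN1, a tight junction protein, fell 2.30-fold, CCDC9 2.26-fold and ERRFI1, an inhibitor of the epidermal growth factor receptor, 2.22-fold. The interferon-induced gene OASL fell 2.17-fold, from 12.22 ± 0.22 to 11.10 ± 0.15. The sulfate transporter SLC26A2 fell 2.08-fold and the iron exporter SLC40A1 fell 2.07-fold, with a mean of -0.69 on its 2 other probe sets against -1.05. The other probe set of SLC20A1 differed by 0.33 against 0.69, that of SOWAHC by 1.67 against 1.07 and that of CLDN1 by -2.23 against -1.20. For each gene named so far, all 5 troglitazone pools lay on the same side of the control mean. The naming rule required this of the largest rises and falls, so it adds no support for them. These genes moved in pools whose ACTB ratio was also higher, 1.34 against 1.19.

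The fits set some limits on these calls. The count of 28 (11 up, 17 down) became 18 (3 up, 15 down) with each array scaled to its median, which moved the median gene from -0.02 to -0.13, and every one of the 28 kept its sign under that scaling, also relative to the median gene. Without a mean-variance trend 4 genes passed, with adjustment within each array type 46 did, and without the 3 pools that correlate least 11 did, 10 of them shared. The count was 17 without control replicate 2, control replicate 3 or troglitazone replicate 2, 18 without control replicate 5 or troglitazone replicate 3, 14 without control replicate 4 and 46 without troglitazone replicate 1. In every fit that left out a pool, 12 of the 28 were called: SLC40A1, SMS, HMOX1, ADAMTS1, ALAS1, PLIN2, CRH, ERRFI1, SOWAHC, SLC26A2, DTX4 and INSIG1. With the ACTB ratio as a covariate 8 of the 28 passed the adjusted threshold, and all 28 had an unadjusted limma p under 0.05. Of the other genes named above, CEBPA and SLC20A1 were called in 9 of the 10 fits that left out a pool, OASL in 8, TGFBR1 and CLDN1 in 3, LIMCH1 and CCDC9 in 2 and CPT1A in 1. Their adjusted p ran up to 0.121 for TGFBR1 and 0.116 for CPT1A. PPARG was called in 1 of these fits, with adjusted p up to 0.102, and its adjusted p was 0.13 without the 3 pools.

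**Figure D1:**
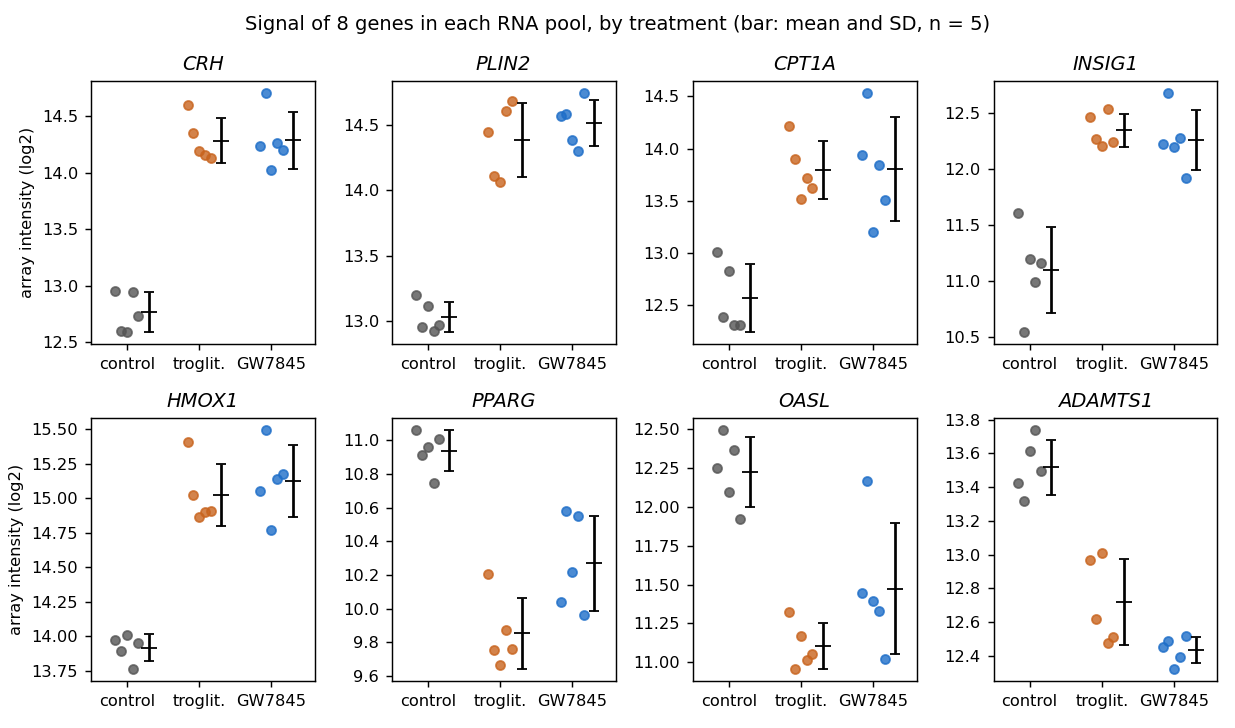
Log2 intensity of 8 named genes in each of the 15 pools, by treatment, with bars for the mean and SD of 5 pools and a separate axis range per gene. CRH and PLIN2 were higher in all 5 pools of each ligand than the control mean, and PPARG was lower in all 5 pools of each ligand, with its change past the threshold for troglitazone.

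By gene list, 3 of 31 lists changed with troglitazone, 2 up and 1 down, while the ACTB ratio was 1.34 against 1.19. Interferon response genes were lower as a list (28 of 32 measured, mean -0.26, adjusted p = 0.000364, and adjusted p = 0.194 with an estimated correlation). Of the 28 members, 0 rose, 1 fell (OASL) and 27 did not pass, and 5 passed when adjusted over the list alone. All 5 pools lay under the control mean (exact permutation p = 0.00794). The list's mean was -0.40 with median scaling, or -0.26 relative to the median gene (adjusted p = 0.000374). Without the 3 pools that correlate least, it was -0.15 and the adjusted p was 0.148. PPAR target genes of lipid metabolism were higher as a list (26 of 32 measured, mean 0.15, adjusted p = 0.04, and adjusted p = 0.173 with an estimated correlation). Of these, 2 rose (PLIN2 and CPT1A), 0 fell and 24 did not pass, and 3 passed when adjusted over the list alone. The exact permutation p of the pool means was 0.0556. With median scaling the list's mean was 0.05, or 0.18 above the median gene (adjusted p = 0.0378). Cell cycle genes were higher as a list (36 of 45 measured, mean 0.18, adjusted p = 0.0406, and adjusted p = 0.194 with an estimated correlation). None of their 36 members passed over all genes and 1 did when adjusted over the list alone. CCND2, a cyclin, differed by 1.23 (SE 0.29, adjusted p = 0.128) and the proliferation marker MKI67, whose signal was dim, by 1.59 (SE 0.48, adjusted p = 0.287). The exact permutation p of the pool means was 0.0714. Leaving out troglitazone replicate 1, 2 or 5 left 1 changed list, the floor at 20% or a replicate block also left 1, and leaving out the 3 pools left 0. The adjusted p of the PPAR target list was then 0.0678, 0.0864 and 0.0858 without those replicates, and 0.0852 without control replicate 5. Among fits that left out 1 pool, the cell cycle call held only without control replicate 4 or control replicate 5, and its adjusted p reached 0.22 without troglitazone replicate 3. It was 0.12 with quantile normalisation, where the list's mean was 0.08, and 0.101 with median scaling, where the mean was 0.00, or 0.13 above the median gene. In fry, which asks whether a list's genes move 1 way without comparing them with other genes, the adjusted p was 0.0358 for interferon response, 0.0216 for PPAR targets and 0.0532 for the cell cycle. Cholesterol synthesis (up) and placental hormones (down) passed in fry alone, at 0.0445 each.

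Other lists did not change as a whole with troglitazone but held changed members. Placental hormones had 1 of 26 up (CRH) and 25 that did not pass. That list as a whole pointed down (mean -0.13, 10 of 26 members positive, adjusted p = 0.129), and 7 members passed when adjusted over the list alone. There were, for regulators of trophoblast fusion, 1 of 27 up (CEBPA), for the oxidative stress response 1 of 29 up (HMOX1) and for cholesterol synthesis 1 of 17 up (INSIG1). Lipid droplet genes had 1 of 21 up (PLIN2), nutrient transporters 1 of 29 up (SLC20A1) and 1 down (SLC40A1), fatty acid oxidation 1 of 21 up (CPT1A), and nuclear receptors 1 of 28 down (PPARG). Adjusted p for these lists ran from 0.0733 (fatty acid oxidation, up) and 0.111 (cholesterol synthesis, up) to 0.802. The test of the oxidative stress list pointed up while its median (-0.04) and mean (-0.04) were negative, and that of the fusion list pointed down while its median was 0.01 and its mean -0.06.

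The comparison of GW7845 with control asked the same of a PPARG agonist at another dose. TLE6, a transcriptional corepressor family member, rose 3.06-fold, CRH rose 2.87-fold and PLIN2 rose 2.79-fold. CPT1A rose 2.36-fold, COL4A1, a basement membrane collagen, rose 2.35-fold, HMOX1 rose 2.31-fold and INSIG1 rose 2.24-fold. ADAMTS1, a secreted metalloprotease, fell 2.12-fold and OLR1, a receptor of oxidised low-density lipoprotein, fell 2.04-fold. In all, 21 genes changed, 16 up and 5 down, and 39 probe sets, 29 up and 10 down.

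TLE6 (95e) stood at 13.90 ± 0.36 with GW7845 and 12.28 ± 0.55 in control, a difference of 1.61 (SE 0.30, adjusted p = 0.0406). CRH stood at 14.29 ± 0.25, a difference of 1.52 (SE 0.13, adjusted p = 1.02e-05), and PLIN2 at 14.51 ± 0.17, a difference of 1.48 (SE 0.13, adjusted p = 1.02e-05). COL4A1 (95e) stood at 14.37 ± 0.22 against 13.14 ± 0.12, a difference of 1.23 (SE 0.17, adjusted p = 0.00296), and its 2 other probe sets had a mean of 0.42. For HMOX1 the difference was 1.21 (adjusted p = 0.000172), for CPT1A 1.24 (SE 0.23, adjusted p = 0.0402) and for INSIG1 1.16 (SE 0.18, adjusted p = 0.0102). The 6 other probe sets of CPT1A had a mean of 0.50. ADAMTS1 (95b) stood at 12.43 ± 0.08 against 13.52 ± 0.16 and fell by 1.08 (SE 0.12, adjusted p = 0.000174). SOWAHC rose 2.39-fold, ETFA, a subunit of the flavoprotein that carries electrons from fatty acid oxidation, 1.83-fold, SLC20A1 1.54-fold and CEBPA 1.5-fold. The metalloreductase STEAP4 fell 1.67-fold, the spermine synthase gene SMS fell 1.64-fold (-0.42 on its other probe set against -0.71) and the folate receptor gene FOLR1 fell 1.44-fold. PPARG stood at 10.27 ± 0.28, with a difference from control of -0.67 (SE 0.20, 95% interval -1.08 to -0.26) that did not pass (adjusted p = 0.313). For each gene named in this comparison, all 5 GW7845 pools lay on the same side of the control mean, as the naming rule required of the largest rises and falls. The ACTB ratio of these pools was 1.44 against 1.19 in control.

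The count of 21 (16 up, 5 down) became 5 (4 up, 1 down) with median scaling, 8 with a floor at 20%, 3 without a mean-variance trend and 36 with array weights, and all 21 kept their sign under median scaling. It was 13 without control replicate 2, 7 without control replicate 3 or GW7845 replicate 1, 9 without control replicate 4, GW7845 replicate 2 or GW7845 replicate 5, and 12 without control replicate 5. HMOX1, ADAMTS1, PLIN2, COL4A1, CRH, SOWAHC and INSIG1, 7 of the 21, were called in every fit that left out a pool. CEBPA and STEAP4 were called in 3 of the 10 such fits, TLE6, CPT1A, ETFA, SLC20A1 and SMS in 2, and OLR1 and FOLR1 in 1. Their adjusted p ran up to 0.129 for TLE6 and 0.143 for FOLR1. With the ACTB ratio as a covariate 0 of the 21 passed the adjusted threshold, and 12 had an unadjusted limma p under 0.05.

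With GW7845, 3 of 31 lists changed, all up, while the ACTB ratio was 1.44 against 1.19. Fatty acid oxidation genes were higher as a list (21 of 29 measured, mean 0.34, adjusted p = 0.00309, and adjusted p = 0.0872 with an estimated correlation). Of the 21 members, 2 rose (CPT1A and ETFA), 0 fell and 19 did not pass, and 5 passed when adjusted over the list alone. The exact permutation p of the pool means was 0.0317. PPAR target genes of lipid metabolism were higher (26 of 32 measured, mean 0.19, adjusted p = 0.00819, and adjusted p = 0.0721 with an estimated correlation), with PLIN2 and CPT1A up and 24 members that did not pass. On this list 4 passed when adjusted over the list alone, and the exact permutation p of the pool means was 0.0794. Without the 3 pools its adjusted p was 0.0582. Oxidative phosphorylation genes were higher (39 of 45 measured, mean 0.14, adjusted p = 0.00819, and adjusted p = 0.579 with an estimated correlation). None of the 39 passed over all genes and 1 did when adjusted over the list alone. ATP5MC3, a subunit of ATP synthase, differed by 0.63 (adjusted p = 0.238) and CYC1, a subunit of respiratory complex III, by 0.45 (adjusted p = 0.313). On the mean of this list, 4 of 5 pools lay above control (exact permutation p = 0.0714). With median scaling its mean was 0.08, or 0.15 above the median gene (adjusted p = 0.0703). The adjusted p was 0.0594 without control replicate 2 and 0.0637 without GW7845 replicate 2. The count of changed lists was 5 with quantile normalisation, with a floor at 20%, without control replicate 3 or without GW7845 replicate 5. In fry the adjusted p was 0.0193 for fatty acid oxidation, 0.00445 for PPAR targets and 0.35 for oxidative phosphorylation. Cholesterol synthesis (up, 0.0268) and cytokines and inflammation (down, 0.0315) passed in fry alone.

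Outside these lists, placental hormones had 1 of 26 members up (CRH) with a list mean of -0.06 (adjusted p = 0.526), fusion regulators 1 of 27 up (CEBPA), the oxidative stress response 1 of 29 up (HMOX1), cholesterol synthesis 1 of 17 up (INSIG1) and lipid droplets 1 of 21 up (PLIN2). Nutrient transporters had 1 of 29 up (SLC20A1) and 1 down (FOLR1), and the extracellular matrix list had 1 of 27 up (COL4A1). As lists these did not pass, with cholesterol synthesis at an adjusted p of 0.0524. Interferon response genes had a mean of -0.14 and an adjusted p of 0.0524.

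**Figure D2:**
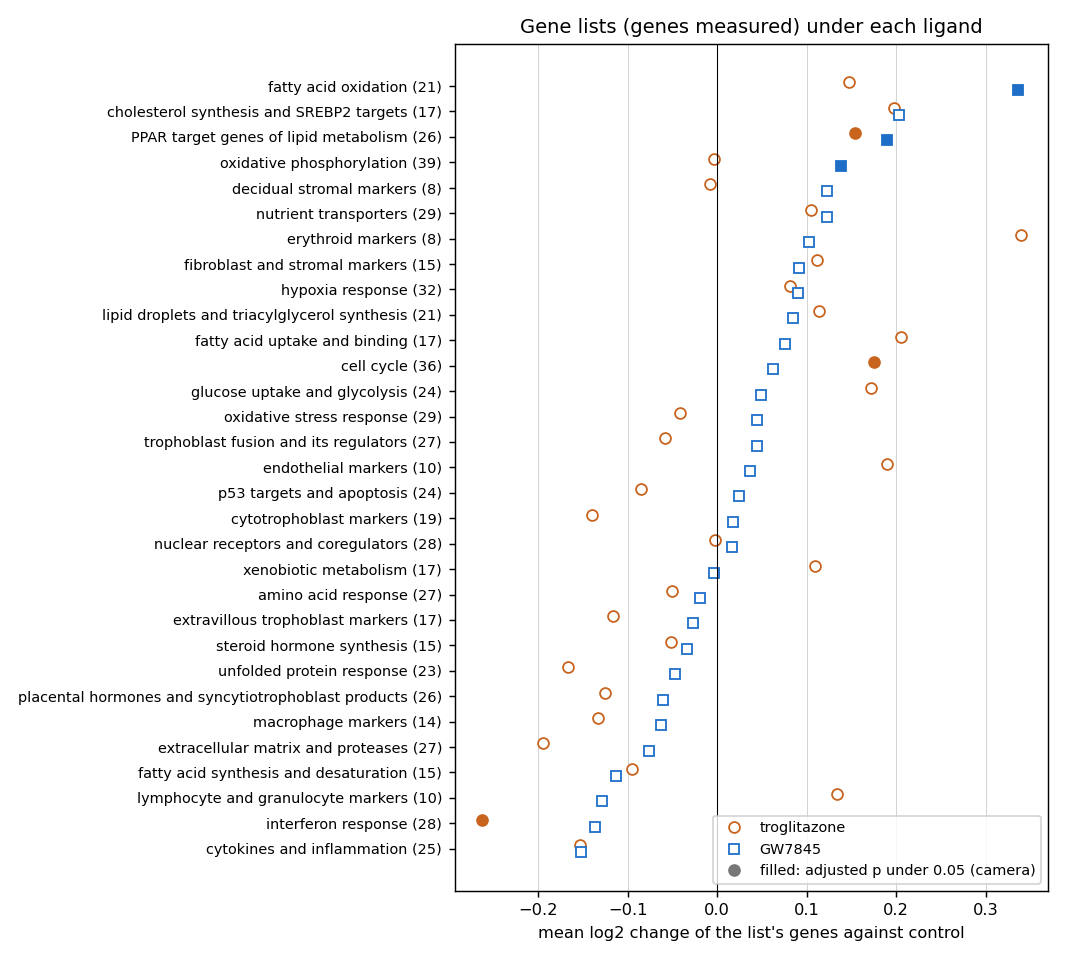
Mean log2 difference from control of the measured genes of each gene list, for troglitazone and for GW7845, with filled symbols for lists past an adjusted p of 0.05 in camera. Interferon response genes were lower with troglitazone (mean -0.26, adjusted p = 0.194 with an estimated correlation), and fatty acid oxidation genes were higher with GW7845 (mean 0.34, adjusted p = 0.0872 with an estimated correlation), and 0 lists passed with an estimated correlation.

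Both ligands changed 13 genes in the same direction, 10 up and 3 down. The 10 were CRH, PLIN2, CPT1A, HMOX1, INSIG1, CEBPA, SLC20A1, SOWAHC, LIMCH1 and ALAS1, the rate-limiting enzyme of heme synthesis, and the 3 were ADAMTS1, STEAP4 and SMS. ALAS1 lies outside the naming rule and was listed after its values were seen, as were ADAMTS1, STEAP4 and SMS for troglitazone and LIMCH1 for GW7845. When 1 pool was left out, STEAP4 was called in 3 of 10 fits for troglitazone, ALAS1 in 5 for GW7845 and LIMCH1 in 1 for GW7845. In simulated data with no change and a shared control, the 28 and 21 genes with the smallest p shared a mean of 2 genes of the same sign (0 to 4 over 20 simulations), a check added after the data were seen. With the control pools split between the ligands, so that no control was shared, a median of 3 genes (range 2 to 4 over 10 splits) were called in both. Each ligand was then compared with only part of the 5 control pools, so fewer genes could pass for each. The drop from 13 thus cannot be put down to the shared control alone. Of the 36 genes called for either ligand, all 36 had the same sign for both, but the shared control gives such agreement by itself. In simulated data with no change, a mean of 96.5% of as many genes with the smallest p had the same sign. With the controls split (a check added after the data were seen), a median of 96.9% of the 4 to 16 genes called for either ligand had the same sign for both (84.6% to 100% over 20 splits).

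Over all 14708 genes, the fold changes of the ligands correlated with r = 0.519 (Spearman rho 0.487, jackknife SE over pools 0.129), across genes, which are not independent replicates. The shared control gives such a correlation by itself: simulated data with no change had a mean r of 0.499. With the controls split, the median r over 20 splits was 0.111 (0.0634 to 0.135).

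**Figure D3:**
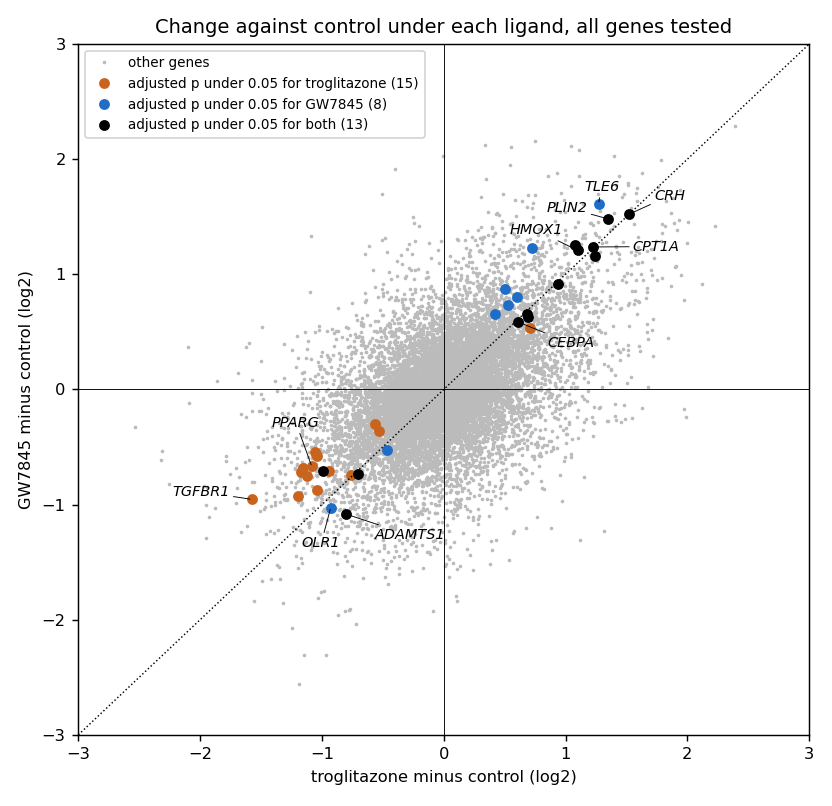
Log2 difference from control with troglitazone (horizontal axis) and with GW7845 (vertical axis) for each of the 14708 genes, with genes past an adjusted p of 0.05 coloured. The 36 coloured genes had the same sign on both axes, which share a control, and 96.5% of the corresponding genes did so in simulated data with no change.

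The direct comparison of GW7845 with troglitazone asked where the responses to the ligands differ, at doses that were not matched (1 µM and 10 µM). CRH differed by 0.00 (95% interval -0.27 to 0.28), PLIN2 by 0.13 (-0.13 to 0.40), CPT1A by 0.01 (-0.47 to 0.49), HMOX1 by 0.11 (-0.16 to 0.37) and INSIG1 by -0.08 (-0.45 to 0.28). PPARG differed by 0.42 (0.01 to 0.82, adjusted p = 0.702). COL4A1 differed by 0.50 (0.16 to 0.85, adjusted p = 0.608), TLE6 by 0.34 (-0.28 to 0.97) and OASL by 0.37 (-0.01 to 0.75). SLC26A2 differed by 0.51 (0.20 to 0.82), SLC40A1 by 0.49 (0.14 to 0.83) and ERRFI1 by 0.47 (0.12 to 0.81). Of the 36 genes called for either ligand, 11 had an unadjusted limma p under 0.05 here. The 36, SLC26A2, SLC40A1 and ERRFI1 among them, were chosen for their change against control in these same pools. That choice by itself favours a difference between the ligands, so neither the 11 nor these intervals count as evidence of one. The lowest adjusted p among the 36 was 0.537.

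In limma, 0 genes and 0 of 31 lists passed in this comparison, with 1101 genes (7.49%) at an unadjusted p under 0.05. The smallest p belonged to CIMAP1B, at 12.18 ± 0.45 with GW7845 and 10.35 ± 0.65 with troglitazone (difference 1.83, adjusted p = 0.26), whose 4 other probe sets had a mean of 0.05. Next came MAD2L1BP (1.74, adjusted p = 0.328), the chemokine CCL7 (-1.37, adjusted p = 0.34) and the semaphorin SEMA5B (-2.43, adjusted p = 0.399). For 7293 genes (49.6%) the 95% interval lay within 1 log2 unit of 0 on both sides. Each interval covers its own gene alone, so larger differences are not excluded for every gene of this set, nor for the other genes. A gene passed without troglitazone replicate 3, troglitazone replicate 4 or GW7845 replicate 4 (1 in each), and 1 list passed with a floor at 20% and without troglitazone replicate 1, troglitazone replicate 5, GW7845 replicate 3 or GW7845 replicate 4.

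None of the lists of cell type markers passed in any comparison. The 8 lists covered cytotrophoblast, extravillous trophoblast, fibroblast and stromal, endothelial, macrophage, erythroid, lymphocyte and granulocyte, and decidual stromal cells. The smallest adjusted p was 0.203 with troglitazone (erythroid markers, 8 of 15 measured, mean 0.34), 0.724 with GW7845 and 0.488 between the ligands.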

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

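The tests of the ACTB ratio, of the pools that correlate least and of the PPARG signal were chosen after the results they concern were seen, and the bounds used for the ACTB ratio by ligand and for the interferon list without 3 pools were set after those values were seen. The test of the ACTB ratio was first run on the genes of both ligands together (median ratio 1.01, jackknife SE 0.108) and then by ligand.

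Among 102 groups of 5 pools, for 34 named genes under 3 treatments, 9 held a pool whose gap to its nearest neighbour exceeded 0.71 of the group's range, against 5.1 by chance. In control pools this share was 0.728 for CYC1 (lowest pool), 0.827 for DTX4 (highest), 0.738 for MAD2L1BP (lowest), 0.822 for OLR1 (lowest) and 0.726 for SEMA5B (highest). With troglitazone it was 0.835 for SMS (lowest) and 0.768 for TGFBR1 (lowest), and with GW7845 0.827 for MKI67 (highest) and 0.744 for TGFBR1 (highest). In probe sets outside the gene comparisons, the 3'/5' ratio of ACTB was 1.34 with troglitazone and 1.44 with GW7845, above the control value of 1.19.

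Genes changed by either ligand differed between groups of pools that also differed in the ACTB ratio, and 3 pools correlated least with the rest. With the ratio as a covariate, the log2 changes of the 28 troglitazone genes had a median ratio of 1.06 (jackknife SE 0.09) to those without it. The changes thus did not shrink with a linear adjustment for the ACTB ratio. The troglitazone pools (1.24 to 1.45) and the control pools (1.15 to 1.24) barely meet in the ratio. The adjustment therefore rests on spread within treatments and cannot rule out RNA quality or labelling for troglitazone. The median size went from 1.05 to 1.07 and the median SE from 0.15 to 0.21, and 20 genes passed, 8 of them among the 28. For the 21 GW7845 genes the median ratio was 0.774 (SE 0.15), the median size went from 0.92 to 0.81 and the median SE from 0.13 to 0.27, and 0 genes passed. An effect of RNA quality and the ligand's effect cannot be told apart for GW7845, because its pools (1.40 to 1.48) and the control pools (1.15 to 1.24) do not overlap in the ratio. The GAPDH ratio, which was not used as a covariate, did not rise with GW7845 (1.46 against 1.55, exact permutation p = 0.135). Leaving out the 3 pools kept a median ratio of 0.987 over both ligands, with all 49 changes above 0.5. For troglitazone, with 3 pools left, it was 0.939 (lowest 0.661), and 10 of the 28 calls remained. That ratio argues against those pools as the whole cause of the troglitazone changes. For GW7845, with 4 pools left, it was 0.996 (lowest 0.886), but the loss of 1 pool could hardly lower it far, so it decides little. An effect of the ligand stays open for both.

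Interferon response genes were lower with troglitazone, a call lost with an estimated correlation (adjusted p = 0.194). The exact permutation p of the pool means was 0.00794, the smallest that 252 splits can give. This p was not adjusted over the 31 lists, and the lists tested were those that camera had called in the same pools. Spread between pools therefore stays open as a cause. Without the 3 pools that correlate least, the mean kept a ratio of 0.578 (-0.15, SE 0.038, 3 against 5 pools, exact permutation p = 0.0357 over 56 splits), and camera's adjusted p was 0.148, against 1.84e-05 to 0.194 over the alternatives. That ratio lies above the bound of 0.5 by less than its spread, so those pools stay open as a source of part of the fall, beside RNA quality, which was not tested on this list, and an effect of the ligand.

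PPARG was lower with troglitazone. Signal near the floor is excluded: the lowest PPARG signal was 813 against a floor of 75 (a ratio of 10.9), and 0 pools lay at the floor. Without the 3 pools the difference kept a ratio of 0.913 (-0.99, SE 0.20), which argues against those pools as the cause, though with fewer pools its adjusted p was 0.13, and it ran up to 0.102 in fits that left out 1 pool. An effect of the ligand on PPARG transcripts is a hypothesis that these data leave open. RNA quality stays open beside it, because the ratio of 1.06 above covers the 28 genes as a set and cannot rule it out.

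Other splits of the same pools into groups of 5 were tried, 100 for each comparison with the real split included. For troglitazone, 1 split (the real one) gave as many as 28 genes, with 1 gene as the highest of the others, and 4 gave as many as 3 lists, with 3 as the highest. For GW7845, 1 split gave as many as 21 genes, with 0 as the highest of the others, and 3 gave as many as 3 lists, with 3 as the highest. Chance is excluded for the gene counts at the 0.05 level. For the lists the shares also lie under 0.05, but other splits also reached a count of 3 lists, and with an estimated correlation 0 lists passed for either ligand. Between the ligands, where 0 genes and 0 lists passed, 100 of 100 splits give as many by construction, so the splits decide nothing there. The highest of the others gave 4 genes and 4 lists.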

How the results depend on the processing

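The fit without 3 pools, the ACTB covariate and the contrast of both ligands with control were chosen after the data were seen. The cause was not tested for any value below, except that a left-out pool leaves fewer samples.

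Genes changed with troglitazone (28) were 18 with median scaling, 4 without a mean-variance trend, 46 with adjustment within each array type, 11 without the 3 pools, and 14 (without control replicate 4) to 46 (without troglitazone replicate 1) when leaving out 1 pool. Genes changed with GW7845 (21) were 5 with median scaling, 8 with a floor at 20%, 3 without a trend, 36 with array weights, and 7 to 19 when leaving out 1 pool. Between the ligands (0) they were 0 to 1. Lists changed with troglitazone (3) were 1 with a floor at 20%, 1 with a replicate block, 0 with an estimated correlation, 0 without the 3 pools and 1 to 3 when leaving out 1 pool. Lists changed with GW7845 (3) were 5 with quantile normalisation, 5 with a floor at 20%, 0 with an estimated correlation and 2 to 5 when leaving out 1 pool. Lists between the ligands (0) were 1 with a floor at 20% and 0 to 1 when leaving out 1 pool. The correlation (0.519) was 0.111 with controls split and 0.470 to 0.567 when leaving out 1 pool. Genes changed with both ligands against control (53) were 30 with a floor at 20% and 20 to 60 when leaving out 1 pool.

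Lists changed with both ligands against control (4) were 0 with an estimated correlation. Genes with the ACTB covariate were 20 for troglitazone (8 shared) and 0 for GW7845. Genes called for both (13) were a median of 3 with controls split, which leaves each ligand fewer control pools. Adjusted p over the alternatives ran from 1.84e-05 to 0.194 for interferon response, 0.000806 to 0.173 for PPAR targets and 0.0297 to 0.362 for the cell cycle with troglitazone, and with GW7845 from 0.000337 to 0.0721 for PPAR targets, 0.000957 to 0.0872 for fatty acid oxidation and 0.00116 to 0.579 for oxidative phosphorylation. A replicate block gave 22, 18 and 0 genes. Correlations between pools of the same number ran from -0.051 to 0.051. Their mean was 0.018 for control and troglitazone (0.007 to 0.051), -0.004 for control and GW7845 and -0.01 for troglitazone and GW7845. Even arrays taken as 1 pool correlated across array types by a median of 0.0505. Such small values cannot decide whether replicate numbers pair the pools. Of 34 changes named as past the threshold, 16 missed it with a floor at 20%, 4 with quantile normalisation and 7 with the replicate block, with signs unchanged in these 3 settings. On the genes' other probe sets, 13 of 19 missed it and LIMCH1 with troglitazone reversed (-0.14). The floor and filter limit what dim probe sets can show: MKI67 with troglitazone differed by 0.64 with the floor at 20%, against 1.59.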

Other observations

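The contrast of the mean of both ligands with control was chosen after the data were seen, and so were its genes.

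Against control, both ligands together changed 53 genes, 26 up and 27 down, among them 18 whose representative probe set did not pass for either ligand alone. The ABC transporter ABCG2, which exports drugs and porphyrins, was higher by 0.59 (adjusted p = 0.0345), SCAP, the escort protein of SREBP, by 0.73 (adjusted p = 0.0229) and SLC25A1, the mitochondrial citrate carrier, by 0.60 (adjusted p = 0.039). Other probe sets of SLC25A1 did pass for each ligand alone (adjusted p down to 0.00475 with troglitazone and 0.00196 with GW7845), and so did another of PIM1 with GW7845 (adjusted p = 0.0243). The lipid transfer protein gene STARD10 was higher by 0.58 (adjusted p = 0.0345) and the kinase PIM1 by 0.48 (adjusted p = 0.039). Lower were the kinase SGK1, which fell by 0.77 (adjusted p = 0.0172), the envelope gene of an endogenous retrovirus ERVV-1, which fell by 0.71 (adjusted p = 0.02), the mucin MUC15, which fell by 0.61 (adjusted p = 0.0344), the chemokine CCL3, which fell by 0.57 (adjusted p = 0.0419), and the interferon-induced gene IFIT3, which fell by 0.54 (adjusted p = 0.0346).

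In this contrast 4 of 31 lists changed: interferon response genes were lower (adjusted p = 0.00261, and adjusted p = 0.223 with an estimated correlation), and PPAR targets (0.00435, and 0.0605 with an estimated correlation), fatty acid oxidation (0.00435, and 0.132) and cholesterol synthesis (0.0405, and 0.132) were higher. Of 100 splits of the 15 pools, 1 (the real one) gave as many as 53 genes, with 1 gene as the highest of the others. For lists, 1 split gave as many as 4, with 3 as the highest of the others. Because the contrast was chosen after the data were seen, these splits do not exclude chance at a stated level. With an estimated correlation 0 lists passed. The ACTB ratio rose with both ligands and stays beside these values. The gene count was 32 without control replicate 2, 31 without control replicate 3, 20 without control replicate 4 and 33 without control replicate 5.

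The bacterial and phage transcripts spiked into the targets as controls were also compared between each ligand and control. Of 40 exact permutation tests, 5 had a p under 0.05, the lowest 0.00794, against 2 expected by chance if the tests were independent, which they are not. In all 5 the spike was higher with the ligand than in control, 4 with troglitazone (BioC on 95b and 95d, BioDn on 95c and 95e) and 1 with GW7845 (BioDn on 95e).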
